A study of Homo sapiens with 5 samples.

How the data were processed

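CLIP-Seq libraries were made from untransfected HEK-293 cells and from HEK-293 cells expressing GFP-(GR)50, GFP-(GP)10 or GFP alone, in 2 independent experiments with 5 libraries in all. Per the labels, cells were crosslinked at 100 mJ/cm2 and 254 nm, lysates were treated with RNase I at 0.04 units/ml in experiment 1 and 0.02 units/ml in experiment 2, and GFP was pulled down on magnetic beads for 1.5 hours. RNA from gel pieces at the size chosen for the fusion, and from the same gel region of the controls, was sequenced as single reads of 110 nt.

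Per the submitters' processing notes, Novoalign 4.03.03, UMI-tools 1.1.2, bedtools 2.30.0, featureCounts 2.0.2 and the builds hg38 and GRCh38.p13 were used. The role and order of these tools, the method that called regions and its filters are not given in the sources used here. The deposited lists hold, for each library separately, the regions called in it with strand, gene, RNA type and repeat annotation. Per the file headers, one column holds the count of reads that map to one place, in the unit count, except in GFP-(GR)50 replicate 2, where 6 of the values are not whole and the deposited unit was taken to be an expected count. Per the file headers, the other column adds multimapping reads scaled by the authors, an expected count (estimated count) whose scaling factor is not given. Neither column is normalised for depth. Both units were checked on the values. The smallest value of the scaled column is 5 in every list, and none of the 3147 regions lies on the mitochondrial chromosome. Coordinates are printed as the files give them, and whether they count from 0 or 1 is not given in the sources used here.

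Each region was given 1 of 14 classes from the deposited annotation: rRNA (genes, pseudogenes and repeat copies), tRNA, snRNA, snoRNA and scaRNA, 7SK RNA, 7SL RNA, Y RNA, other small RNA, protein-coding exon, protein-coding intron, lncRNA, pseudogene, repeat element, or no feature. RN7SK, which the deposited types also name an snRNA, was classed as 7SK RNA. Gene names were those of the annotation. A region annotated as a structured RNA counted for that RNA alone, and 832 regions carry no gene name. Unannotated regions of an extra contig present in experiment 2 were counted as matching rRNA when at least 100 bp wide and within 5 bp in width and within 5% or 2 reads in read count of an annotated rRNA region of the same list. This rule was set after seeing the data. Shares outside rRNA leave these regions out. Regions elsewhere without an rRNA annotation are not covered by the rule, also where they lie inside an rRNA repeat, and stay in those shares.

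Each GFP-(GR)50 library was compared with the controls of its own experiment: replicate 1 with GFP, and replicate 2 with untransfected cells and with GFP-(GP)10. The comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. Region shares were compared with two-sided Fisher's exact tests, adjusted by Benjamini-Hochberg over 3 comparisons for rRNA and for exonic shares and over 42 tests for classes. Overlap meant at least 1 bp on the same strand and was compared with two-sided exact McNemar tests over 6 tests. The 16 gene lists were nuclear rRNA, mitochondrially encoded genes, cytosolic ribosomal proteins, snoRNA and scaRNA, snRNA, 7SL with 7SK, Y, vault, RPPH1 and RMRP, tRNA, nucleolar and ribosome biogenesis factors, translation factors, hnRNP and SR splicing factors, stress granule proteins, nuclear lncRNA, heat shock and chaperones, histones, cytoskeleton, and ALS and FTD genes. Each was tested by names with a region against other names with a region, over 39 tests and over the list alone within each comparison. The threshold was an adjusted p of 0.05. The exonic share of protein-coding regions stands in for position in transcripts, since the files do not separate coding sequence from untranslated regions. Differences in effect between the experiments were tested with an exact test of homogeneity of odds ratios.

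Shares have exact Clopper-Pearson 95% intervals on reads rounded to whole numbers. Odds ratios have 95% intervals from the standard error of their logarithm (Woolf), with 0.5 added to each count where one is 0, and ratios of reads have intervals made from the exact interval of the share. All cover counting error alone, and scaled multimapping reads are not independent reads, so the intervals are too narrow for read shares. Listed reads ran from 7468 in GFP-(GP)10 to 134222 in GFP-(GR)50 replicate 2, and reads that map to one place from 1522 to 9229. Total library depths are not given in the sources used here.

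The text names up to 25 genes with a region in both GFP-(GR)50 lists and in no control, ordered by the worse of their 2 ranks by listed reads. It also names the 5 highest ranked names of each list, up to 4 members of each gene list with a region in at least 2 libraries, and the copies of the rRNA repeat on chromosome 21 with a region in GFP-(GR)50 replicate 2 that holds 18S and 28S rRNA or carries the name of a 45S gene. Copies on contigs whose names are accessions are described without them.

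Alternatives were the regions at or above each list's median reads, the same number of top regions (183) from each list, the 3 control lists together, rRNA genes alone, weights by covered length, regions outside rRNA, overlap of 50% of both regions, overlap on either strand, regions extended by 50 bp, names with at least 2 regions, the region in place of the gene, and each control or GFP-(GR)50 replicate left out. Chosen after seeing the data were matching regions counted as rRNA, uniquely mapping reads, every gene name a region carries, no regions in or opposite repeats, regions of 5 to 7 reads, all uniquely mapping reads as the denominator at RN7SK, libraries as units with experiment as a block, the same number of top protein-coding regions from each list of a comparison, and 7SK regions with at least 5 uniquely mapping reads. The block was tested by permuting libraries within experiments, with all 6 arrangements.

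No count model was fitted, because each list holds the regions called in that library and gives no count elsewhere. Sequence composition of the regions was not analysed here, since no genome sequence was held. The tests were checked on simulated data in which regions were drawn independently. With the control's rRNA share of regions doubled, the rise was recovered in 93%, 90% and 100% of 200 draws for the 3 comparisons. Without a rise, any false call appeared in 4%, 3% and 1.5% of draws. Regions of near-identical copies share reads and are not independent, so these draws do not give the rate of false calls in the real lists. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.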

Results

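RNA bound to GFP-(GR)50, a fusion of GFP with 50 glycine-arginine repeats, was measured by CLIP-Seq in HEK-293 cells, a human embryonic kidney line. Poly-GR is a dipeptide-repeat protein made from the expanded C9ORF72 repeat found in ALS and FTD. In CLIP-Seq, RNA is crosslinked to protein with ultraviolet light, partly digested with RNase, pulled down with the protein and sequenced. There were 5 libraries from 2 experiments. Experiment 1 held GFP-(GR)50 replicate 1 and 1 GFP library, with RNase I at 0.04 units/ml. Experiment 2 held GFP-(GR)50 replicate 2, 1 untransfected library and 1 library of GFP-(GP)10, a fusion with 10 glycine-proline repeats, with RNase I at 0.02 units/ml.

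Each library has a list of bound regions with a read count, in which reads that map to several places were scaled by the authors. The GFP list held 472 regions over 129689 bp with 30598 reads. GFP-(GR)50 replicate 1 held 183 regions over 123229 bp with 56588 reads. The untransfected list held 1339 regions over 180729 bp with 22519 reads, and the GFP-(GP)10 list held 348 regions over 98680 bp with 7468 reads. GFP-(GR)50 replicate 2 held 805 regions over 203918 bp with 134222 reads. Between 2.83% (GFP-(GR)50 replicate 1) and 38.2% (untransfected) of these reads mapped to one place. No region had fewer than 5 reads, so a gene without a listed region is not a gene with 0 reads, and the listed total is not the depth of the library. Each control has a single library, so every test below compares the regions or reads of 2 lists, and its p-value measures the spread of regions or reads alone, not that between cultures. Intervals of shares are exact Clopper-Pearson 95% intervals of counting error, and those of odds ratios come from the standard error of their logarithm.

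The first comparison asks how much of the RNA recovered with poly-GR is ribosomal RNA (rRNA), the RNA of the ribosome, beside the background recovered from control cells. In both GFP-(GR)50 lists rRNA took a larger share of the listed reads than in every control list of the same experiment. The share was 97.1% (97.0 to 97.2) in GFP-(GR)50 replicate 1 against 64.0% (63.4 to 64.5) in GFP. It was 75.6% (75.4 to 75.8) in GFP-(GR)50 replicate 2 against 43.4% (42.7 to 44.0) in untransfected cells and 57.5% (56.4 to 58.7) in GFP-(GP)10. The mean of the GFP-(GR)50 libraries was 86.4% ± 15.2 (SD, n = 2). For every listed read outside rRNA there were 33.6 rRNA reads in GFP-(GR)50 replicate 1 and 1.78 in GFP, a ratio of 18.9. The corresponding values were 3.10 in GFP-(GR)50 replicate 2, 0.766 in untransfected cells and 1.36 in GFP-(GP)10, ratios of 4.05 and 2.29. With the matching regions described below counted as rRNA they were 18.2, 1.19 and 2.62, ratios of 15.3 and 6.93.

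Regions called as rRNA covered 110984 bp in GFP-(GR)50 replicate 1, with a mean of 495 reads per kb, against 95725 bp and 204 reads per kb in GFP. They covered 121639 bp with 834 reads per kb in GFP-(GR)50 replicate 2, 80919 bp with 121 reads per kb in untransfected cells and 63261 bp with 67.9 reads per kb in GFP-(GP)10. Regions not annotated as rRNA, those of the extra contig described next included, had 133 reads per kb in GFP-(GR)50 replicate 1, 325 in GFP, 398 in GFP-(GR)50 replicate 2, 128 in untransfected cells and 89.5 in GFP-(GP)10. In experiment 2, an extra contig outside the named chromosomes carries no annotation, but most of its regions have the width and read count of an annotated rRNA region. With these counted as rRNA, the shares of reads were 94.8% in GFP-(GR)50 replicate 2, 54.2% in untransfected cells and 72.4% in GFP-(GP)10, and the GFP-(GR)50 mean was 96.0% ± 1.64 (SD, n = 2). Among reads that map to one place the shares were 85.9% in GFP-(GR)50 replicate 1, 6.95% in GFP, 48.0% in GFP-(GR)50 replicate 2, 2.82% in untransfected cells and 4.66% in GFP-(GP)10.

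Counted by regions, 114 of 183 (62.3%) lay in rRNA in GFP-(GR)50 replicate 1 against 79 of 472 (16.7%) in GFP, a difference of 45.6 percentage points (adjusted exact p = 1.88e-28, two-sided Fisher's exact test, 3 comparisons). In experiment 2, 119 of 805 regions (14.8%) lay in rRNA in GFP-(GR)50 replicate 2 against 62 of 1339 (4.63%) in untransfected cells, a difference of 10.2 points (adjusted exact p = 1.91e-15). Against GFP-(GP)10, with 66 of 348 (19.0%), the difference was -4.18 points and did not pass the test (adjusted exact p = 0.0807). That last difference turned to 15.3 points when the same number of top regions, 183, was taken from each list (adjusted exact p = 0.00352) and to 5.19 points against the 3 control lists together. It passed in the other direction with matching regions counted as rRNA, at -8.00 points (adjusted exact p = 0.00138), and with annotated rRNA genes alone, at -9.35 points (adjusted exact p = 2.08e-12). Such genes had 8 regions with 49.3% of reads in GFP-(GR)50 replicate 2 and 36 regions with 37.8% in GFP-(GP)10. The copy RNA45SN1 was 1 region with 12735 reads in the former and 7 regions with 552 reads in the latter. Fewer regions there thus went with more rRNA reads, since a continuous stretch is counted as 1 region. With annotated rRNA genes alone, the first difference fell to 3.59 points (adjusted exact p = 0.0661) and the second turned to -0.724 points. This setting leaves out scattered copies, where 79 of the 114 and 93 of the 119 rRNA regions lay. It also leaves out regions of the rRNA repeat without an rRNA gene name, such as 1 of 4519 reads on RNA45SN2 in GFP-(GR)50 replicate 1. That list kept 12 regions with 46.6% of reads, so the fall is not due to scattered copies alone.

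**Figure D1:**
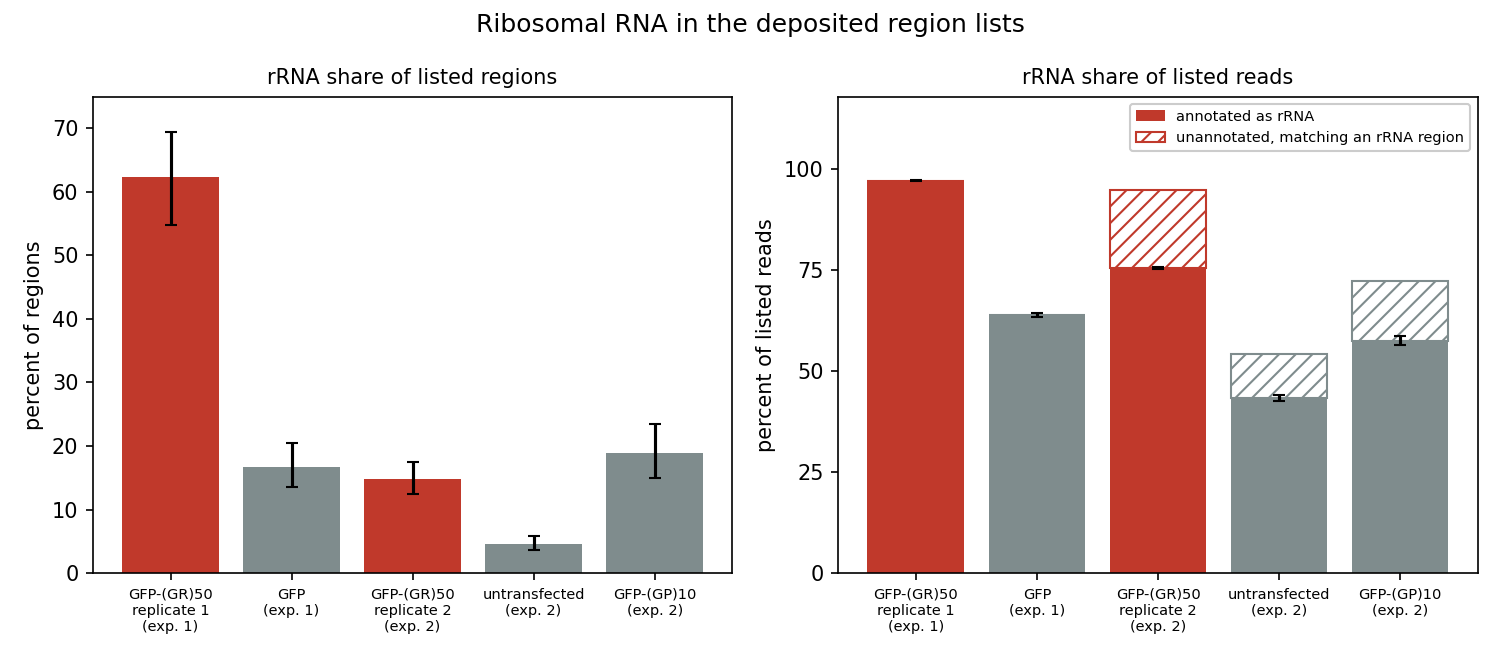
Share of listed regions (left, percent) and of listed reads (right, percent) in rRNA for each of the 5 libraries, GFP-(GR)50 in red and controls in grey, with exact 95% Clopper-Pearson intervals of the annotated share as error bars. Hatched parts add unannotated regions of the extra contig that match an rRNA region; the GFP-(GR)50 libraries reach 97.1% and 94.8% of reads, above the 54.2% to 72.4% of the controls.

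Along the rRNA gene repeat, the regions of the GFP-(GR)50 lists ran nearly without gaps over the 45S precursor, the transcript from which 18S, 5.8S and 28S rRNA are matured. The control lists left more gaps on the copies with gene names, but they also had fewer reads there, and with a minimum of 5 reads per region fewer reads alone leave gaps, so no difference in binding along the precursor can be read from the coverage. On the copy RNA45SN1, GFP-(GR)50 replicate 2 had 1 region with 12735 reads on chromosome 21 from 8433220 to 8446606 (hg38, as the files give them). This region of 13386 bp was taken as the span of the copy, so replicate 2 covers 100% of it by construction. Listed regions covered 98.6% of it with 7092 reads in GFP-(GR)50 replicate 1. The controls covered 86.7% with 2444 reads in GFP, 80.6% with 1220 reads in untransfected cells and 63.1% with 552 reads in GFP-(GP)10. The first listed base lay 2 bp from the start of this span in GFP-(GR)50 replicate 1, 428 bp in GFP, 265 bp in untransfected cells and 635 bp in GFP-(GP)10. The copies RNA45SN2 (chromosome 21, 8205986 to 8219336) and RNA45SN3 (chromosome 21, 8389033 to 8402377), with spans set the same way, showed covered shares of 98.0% and 95.9% in GFP-(GR)50 replicate 1, 99.6% and 98.1% in GFP-(GR)50 replicate 2, 85.3% and 80.7% in GFP, 80.0% and 79.3% in untransfected cells and 62.3% and 60.5% in GFP-(GP)10. A further stretch without a gene name (chromosome 21, 8252769 to 8260984) had 8254 reads in GFP-(GR)50 replicate 2, whose region sets its span. It was covered to 96.9% with 4536 reads in GFP-(GR)50 replicate 1, 96.99% with 1616 reads in GFP, 79.0% with 946 reads in untransfected cells and 63.6% with 411 reads in GFP-(GP)10.

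The 5′ external transcribed spacer, the leading part of the precursor that is removed during maturation, held a larger part of the listed reads in the GFP-(GR)50 lists. The minimum of 5 reads may account for this, since the controls list 1929, 1848 and 894 of the 3234 bp of the stretch on RNA45SN2, in the order GFP, untransfected and GFP-(GP)10, and reads below the minimum are not counted. On the RNA45SN2 copy, the stretch from 8205986 to 8209220 held 3.41% (3.00 to 3.87) of the copy's reads in GFP-(GR)50 replicate 1 against 1.33% (0.915 to 1.88) in GFP. It held 5.16% (4.78 to 5.56) in GFP-(GR)50 replicate 2, 1.69% (1.01 to 2.54) in untransfected cells and 0.998% (0.297 to 2.12) in GFP-(GP)10. On the RNA45SN3 copy the shares were 2.97%, 0.838%, 4.62%, 1.66% and 0.981% in the same order. The part with 28S rRNA held 2.49 times (2.37 to 2.63) the reads of the part with 18S rRNA on RNA45SN2 in GFP-(GR)50 replicate 1 and 0.993 times (0.916 to 1.08) in GFP. This ratio was 1.65 in untransfected cells and 2.15 in GFP-(GP)10, so controls differed in it too, and in GFP-(GR)50 replicate 2 the parts lie in 1 region and cannot be separated. The stretches are regions of GFP-(GR)50 replicate 2 chosen after their values were seen, regions that run more than 40 bp past their end are not counted in them (the region of GFP-(GR)50 replicate 1 on RNA45SN2 runs to 8209227 and is counted), and reads from all near-identical copies are shared among them.

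**Figure D2:**
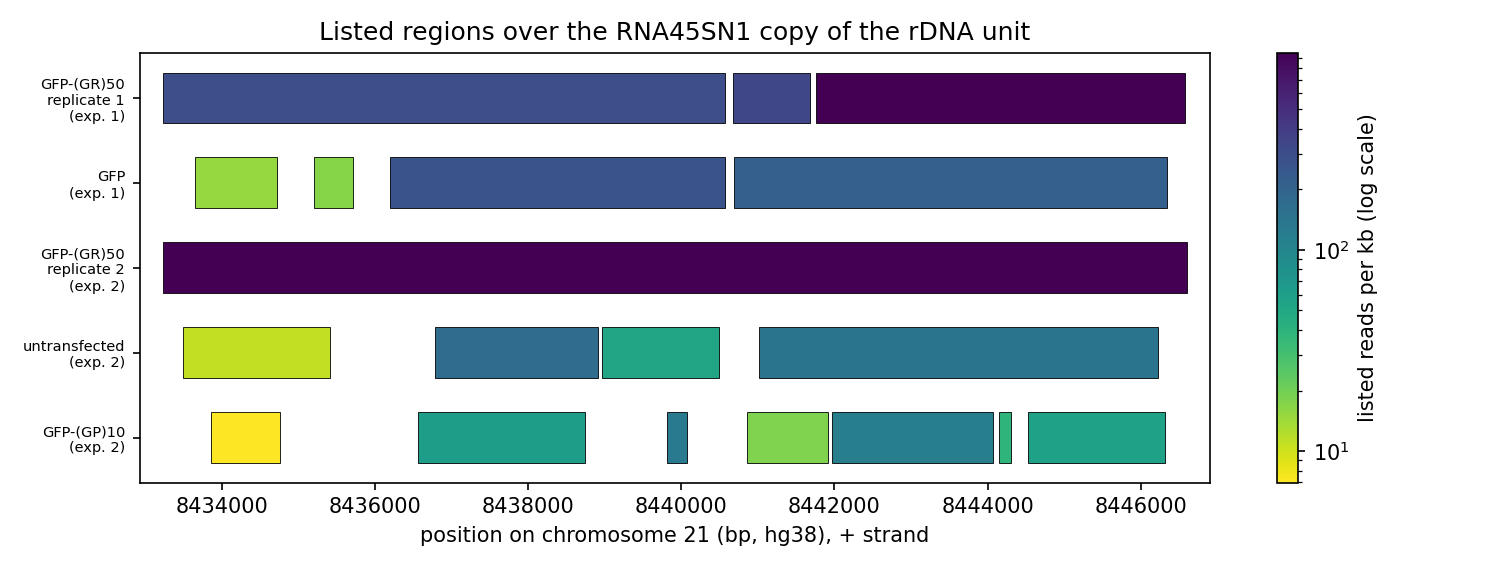
Map of listed regions on the plus strand of the RNA45SN1 copy of the rRNA gene repeat (x axis, position on chromosome 21 in bp, hg38) for each library, coloured by listed reads per kb on a log scale. The 1 region of GFP-(GR)50 replicate 2 sets the span, and regions cover 98.6% of it in GFP-(GR)50 replicate 1 and 63.1% to 86.7% in the controls.

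Outside rRNA, the next comparison asks which other classes of RNA came with poly-GR. Against GFP, GFP-(GR)50 replicate 1 had fewer regions in tRNA, the adaptors of translation, and more in 7SK RNA, the small nuclear RNA that restrains the elongation factor P-TEFb. tRNA took 4 of 183 regions (2.19%) against 230 of 472 (48.7%) in GFP (adjusted exact p = 1.04e-34). 7SK RNA took 10 regions against 4 (adjusted exact p = 0.00278), a call lost among regions with at least 5 uniquely mapping reads (2.08 points, adjusted exact p = 0.253). With rRNA, which was higher, 3 of 14 classes passed the threshold of 0.05 over all 42 tests (two-sided Fisher's exact tests with Benjamini-Hochberg adjustment). U1 and other snRNA took 16 regions against 48, 8.74% and 10.2% of each list. Among reads outside rRNA, tRNA took 76.2% (75.4 to 77.0) in GFP and 2.23% (1.55 to 3.04) in GFP-(GR)50 replicate 1, where 47.7% of these reads had no annotated feature. Some of the latter may be rRNA precursor. Replicate 1 listed regions of 139 and 28.7 reads without a name inside the unnamed rRNA stretch on chromosome 21. The exon share of regions did not pass over all regions (2.29 points, adjusted exact p = 0.346), but it passed outside rRNA (10.7 points, adjusted exact p = 0.00530). It also passed at the same number of top regions (5.46 points, adjusted exact p = 0.00796), which decides nothing. There GFP-(GR)50 replicate 1 enters whole and the cut leaves GFP 0 exonic regions. Those of GFP had at most 8.5 reads, below the median of 12.2 of its list.

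Against untransfected cells, GFP-(GR)50 replicate 2 had more regions in 7SK RNA, tRNA, snoRNA and scaRNA (guides of RNA modification), and exons of protein-coding genes, and fewer in introns, repeat elements and unannotated sequence. 7SK RNA took 26 of 805 regions against 1 of 1339 (adjusted exact p = 6.16e-10), tRNA 39 against 7 (adjusted exact p = 2.48e-10) and snoRNA and scaRNA 14 against 5 (adjusted exact p = 0.00470). Exons took 96 regions, 11.9%, against 44, 3.29% (adjusted exact p = 1.99e-13). Introns took 187, 23.2%, against 426, 31.8% (adjusted exact p = 8.15e-05). Repeat elements took 123 against 335 (adjusted exact p = 3.09e-07) and unannotated sequence 113 against 346 (adjusted exact p = 3.27e-10). With rRNA, 8 of 14 classes passed. At the same number of top regions from each list 4 passed and the exon difference turned to -0.546 points. There the differences of snoRNA (1.64 points), introns (-3.83 points) and unannotated sequence (-9.84 points) no longer passed. Without regions opposite a repeat element, an alternative chosen after seeing the data, these 3 also did not pass. They were then 1.63 points for snoRNA, -3.36 for introns and -1.31 for unannotated sequence.

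Against GFP-(GP)10, GFP-(GR)50 replicate 2 had more regions in 7SK RNA and in exons and fewer in tRNA. 7SK RNA took 26 regions against 1 of 348 (adjusted exact p = 0.00345), a call lost among regions with at least 5 uniquely mapping reads (1.12 points, adjusted exact p = 0.310). Exons took 96 against 13, 3.74% (adjusted exact p = 2.08e-05). tRNA took 39 regions, 4.84%, against 68, 19.5% (adjusted exact p = 5.23e-13). These were 3 of 14 classes. In experiment 2 the tRNA share of GFP-(GR)50 thus lay below that of GFP-(GP)10 and above that of untransfected cells. At the same number of top regions 5 classes passed, and the exon difference turned to -1.09 points. The snRNA share, which did not pass over all regions, was higher there by 7.65 points (adjusted exact p = 0.00214), and by 7.61 points in the regions at or above each list's median reads (adjusted exact p = 0.000271). U1 copies such as RNU1-1 and RNU1-2 had 17.8 and 17.7 reads in GFP-(GR)50 replicate 2 and 5.50 each in GFP-(GP)10, with 0 uniquely mapping reads. Such copies share reads and pass a cut together, so these tests count 1 RNA as several regions.

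The tRNA names with the most reads show the levels behind these shares, each by its best region. The tRNA-Glu-GAG region on chromosome 13 (44917920 to 44917980 in the GFP list) had 568 reads in GFP and 7.25 in GFP-(GR)50 replicate 1, 35 in GFP-(GP)10 and 25 in GFP-(GR)50 replicate 2. The tRNA-Arg-CGA region on chromosome 15 (89335099 to 89335146) had 304 reads in GFP and no listed region in GFP-(GR)50 replicate 1, and 8 in untransfected cells, 32 in GFP-(GP)10 and 50 in GFP-(GR)50 replicate 2. tRNA-Lys-AAA reached 255 reads in GFP, 16.1 in GFP-(GR)50 replicate 1, 8.20 in untransfected cells, 31.8 in GFP-(GP)10 and 26.5 in GFP-(GR)50 replicate 2. tRNA-Asn-AAC had 264 reads in GFP, 26.6 in GFP-(GP)10 and 17.7 in GFP-(GR)50 replicate 2. These are listed reads from lists of unequal depth and were not tested gene by gene.

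**Figure D3:**
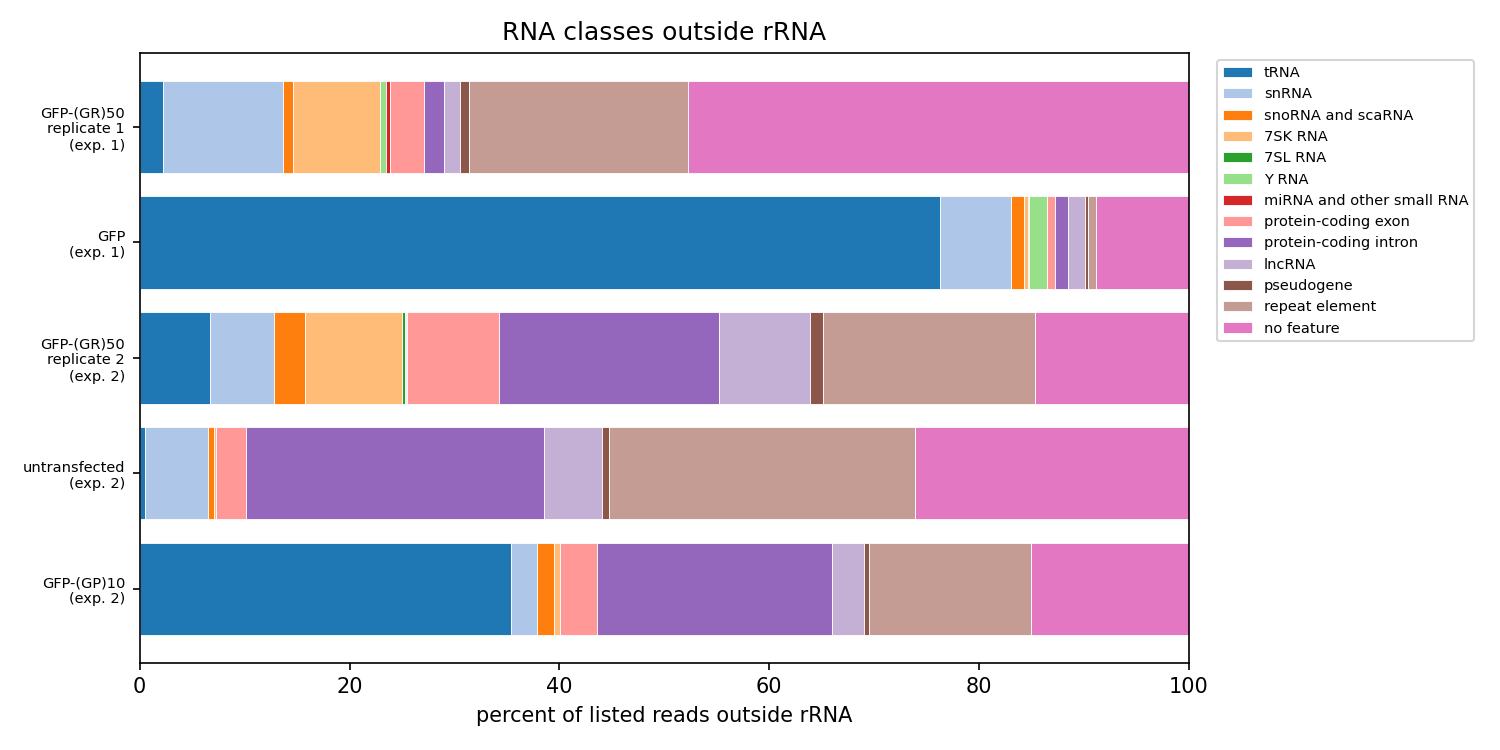
Share of listed reads outside rRNA (x axis, percent; matching regions of the extra contig left out) taken by each of the other RNA classes in each library, without error bars. tRNA takes 76.2% in GFP, 35.4% in GFP-(GP)10 and 2.23% and 6.74% in the GFP-(GR)50 libraries, and 7SK RNA takes 8.30% and 9.18% in the GFP-(GR)50 libraries.

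7SK RNA took a larger share of reads in both GFP-(GR)50 lists than in their controls, by a margin that depends on whether rRNA reads are counted. Of all listed reads it took 0.240% (0.202 to 0.284) in GFP-(GR)50 replicate 1 against 0.146% (0.107 to 0.197) in GFP, and 0.478% (0.442 to 0.517) in GFP-(GR)50 replicate 2 against 0.0679% (0.0373 to 0.110) in untransfected cells and 0.146% (0.0736 to 0.263) in GFP-(GP)10. It took 8.30% (7.03 to 9.77) of the reads outside rRNA in GFP-(GR)50 replicate 1 against 0.405% (0.298 to 0.546) in GFP, and 9.18% (8.51 to 9.88) in GFP-(GR)50 replicate 2 against 0.148% (0.0815 to 0.240) in untransfected cells and 0.529% (0.267 to 0.953) in GFP-(GP)10. The RN7SK gene (chromosome 6, 52995617 to 52995952) had 36.4 reads in GFP-(GR)50 replicate 1, 28.4 in GFP, 163 in GFP-(GR)50 replicate 2, 15.3 in untransfected cells and 10.9 in GFP-(GP)10. In experiment 1 this was 36.4 of 56588 listed reads in GFP-(GR)50, a smaller share than the 28.4 of 30598 in GFP. The larger 7SK share of replicate 1 came from copies outside RN7SK, with 99.3 reads against 16.3 in GFP. Of reads that map to one place outside rRNA, 5 of 226 lay at RN7SK in GFP-(GR)50 replicate 1 and 8 of 5797 in GFP, an odds ratio of 16.4 (5.31 to 50.4; adjusted exact p = 0.000107, exact test). In GFP-(GR)50 replicate 2 it was 58 of 4802, against 7 of 8363 in untransfected cells, an odds ratio of 14.6 (6.66 to 32.0; adjusted exact p = 3.05e-18), and 5 of 1451 in GFP-(GP)10, an odds ratio of 3.54 (1.42 to 8.83; adjusted exact p = 0.00240). Over all reads that map to one place, rRNA included, the odds ratios were 2.43 (0.795 to 7.45; adjusted exact p = 0.203), 7.77 (3.54 to 17.03; adjusted exact p = 4.21e-10) and 1.92 (0.768 to 4.79; adjusted exact p = 0.203), so only the difference from untransfected cells passed both ways. The tests at RN7SK were chosen after the 7SK counts were seen.

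The files annotate genes as exon or intron and do not separate coding sequence from untranslated regions, so position in protein-coding genes was compared as the exonic share. In GFP-(GR)50 replicate 2, 96 of 283 protein-coding regions (33.9%, 28.4 to 39.8) lay in exons. The share was 44 of 470 (9.36%, 6.88 to 12.4) in untransfected cells, an odds ratio of 4.97 (3.34 to 7.39; adjusted exact p = 4.58e-16), and 13 of 88 (14.8%, 8.11 to 23.9) in GFP-(GP)10, an odds ratio of 2.96 (1.56 to 5.61; adjusted exact p = 0.000683). In experiment 1 it was 10 of 16 (62.5%) in GFP-(GR)50 replicate 1 against 15 of 35 (42.9%) in GFP (adjusted exact p = 0.237, exact tests throughout). Among genes with exonic regions in GFP-(GR)50 replicate 2, chosen after their values were seen, EEF2, the elongation factor that moves the ribosome along, had 6 regions with 47.9 reads in all, and it also had 1 region in GFP. RPL13 (16.5 reads), RPLP2 (13.8 reads), RPS3 (10.8 reads), RACK1 (10.3 reads), ACTG1 (12 reads), DDX17 (11 reads) and WDR90 (11 reads) had 2 each, and GNAS had 1 with 16.1 reads.

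Among the regions at or above each list's median reads, the difference from untransfected cells was 23.3 points (adjusted exact p = 2.76e-05). At the same number of top regions, only 2 of 12 protein-coding regions of GFP-(GR)50 replicate 2 were exonic against 3 of 20 in untransfected cells, a difference of 1.67 points (p = 1, exact), and 4 of 22 in GFP-(GP)10, a difference of -1.52 points, too few regions to decide. With as many top protein-coding regions from each list, an alternative chosen after the values were seen, 96 of 283 were exonic against 23 in untransfected cells. The odds ratio was 5.803 (3.55 to 9.49, adjusted exact p = 6.75e-14). There the GFP-(GR)50 list enters whole, against at most 44 exonic regions of untransfected cells, so this value decides nothing. In the comparison with GFP-(GP)10, 27 of 88 were exonic against 13, an odds ratio of 2.55 (1.21 to 5.37, adjusted exact p = 0.0280). Against GFP-(GP)10 the difference did not pass among the regions at or above each list's median reads (14.7 points, adjusted exact p = 0.288) or without regions in or opposite repeats (21.7 points, adjusted exact p = 0.317).

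The next comparison asks whether the GFP-(GR)50 experiments share more regions with each other than with the controls. Of the 183 regions of GFP-(GR)50 replicate 1, 150 (82.0%, 75.6 to 87.3) overlapped a region of GFP-(GR)50 replicate 2 on the same strand, 102 (55.7%) one of GFP, 73 (39.9%) one of untransfected cells and 61 (33.3%) one of GFP-(GP)10. The GFP-(GR)50 overlap was larger than each (adjusted exact p = 4.86e-10, 8.24e-21 and 4.46e-25, two-sided exact McNemar tests, 6 tests). Of the 805 regions of GFP-(GR)50 replicate 2, 130 (16.1%) overlapped replicate 1, which is fewer than overlapped GFP (159, 19.8%, adjusted exact p = 0.0227) or untransfected cells (207, 25.7%, adjusted exact p = 7.63e-07). For GFP-(GP)10 the number was 121 (15.03%, adjusted exact p = 0.538). With 183 top regions from each list the order turned: 59.0% of the top regions of GFP-(GR)50 replicate 2 overlapped replicate 1, 27.3 points more than GFP, 29.5 more than untransfected cells and 34.4 more than GFP-(GP)10 (adjusted exact p = 5.04e-09, 3.85e-09 and 2.49e-10). Outside rRNA, 39 of 69 regions of GFP-(GR)50 replicate 1 overlapped replicate 2 and 33 overlapped GFP, a difference of 8.70 points (adjusted exact p = 0.238). Of the 682 regions of replicate 2 outside rRNA, 39 (5.72%) overlapped replicate 1, fewer than overlapped GFP (102, 14.96%, adjusted exact p = 8.14e-12), untransfected cells (164, 24.05%, adjusted exact p = 1.87e-23) or GFP-(GP)10 (90, 13.2%, adjusted exact p = 2.93e-07). But replicate 1 held only 69 regions outside rRNA, against 393 in GFP, 1267 in untransfected cells and 267 in GFP-(GP)10. The shorter list alone can give fewer overlaps, so these tests do not show less sharing between the GFP-(GR)50 libraries.

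Of the 80 names with a region in GFP-(GR)50 replicate 1 and the 484 in replicate 2, 47 were shared, and 13 of these had no region in any control. Some names of the rRNA repeat could not match, since the lists of experiment 1 use older names for its copies. The 13 names fall into groups that repeat the classes above. MIR3648-1 (chromosome 21, 8205986 to 8209220 in replicate 2) and MIR3648-2 (chromosome 21, 8986603 to 8988752) are microRNA names inside the 5′ spacer of the rRNA precursor, with 240 and 458 reads in replicate 1 and 654 and 786 in replicate 2. The stretch of MIR3648-1 was not free of control reads. GFP had 3 regions with 32.0 reads there, untransfected cells 2 with 20.4 and GFP-(GP)10 1 with 5.47, none with that name. There were 7 copies of 7SK RNA: RN7SKP203 (chromosome 2, 76445184 to 76445411) led with 23.4 and 58.6 reads, followed by RN7SKP71 (13.8 and 32.4 reads), RN7SKP90 (7.50 and 30.2), RN7SKP79 (6.69 and 24.3), RN7SKP9 (5.92 and 36.6), RN7SKP230 (5.72 and 36.8) and RN7SKP180 (5.25 and 10.96). MTRNR2L8 (chromosome 11, 10507887 to 10507968) and MTRNR2L4 (chromosome 16, 3371918 to 3372011), nuclear genes that resemble mitochondrial 16S rRNA, had 6.57 and 14.3 reads and 5.47 and 6.10 reads. Only 1 and 2 of these reads mapped uniquely at MTRNR2L8 and 0 at MTRNR2L4. The like-named MTRNR2L1 had 1 exonic region of 7.5 reads in GFP, so absence from the controls may not hold for the family. The lncRNA MIR663AHG (chromosome 20, 26209294 to 26209627) had 12.2 and 45.9 reads, and introns of DAZAP1, an RNA-binding protein gene, had 7 and 5 reads at separate places. In 7SK copies outside RN7SK, 10.1% and 20.05% of the reads map to one place in replicates 1 and 2, and the rest are shared between copies. Taking the region as the unit, 53 regions of GFP-(GR)50 replicate 1 overlapped replicate 2 and no control, and 41 of them were rRNA.

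The highest ranked names of every list were those of the rRNA repeat, with LSU-rRNA_Hsa, the repeat annotation of 28S rRNA, first. In GFP-(GR)50 replicate 1 the next were RNA28S5 and RNA45S5, whose best region, on an annotated contig outside the named chromosomes, held 4913 reads, and RNA28S4 and RNA45S4 on chromosome 21 (8441763 to 8446586) with 4582 reads. In GFP they were the same names, with 1390 and 1227 reads. In GFP-(GR)50 replicate 2 RNA18SN4, RNA28SN4, RNA45SN4 and RNA5-8SN4 shared 1 region of 14665 reads. In untransfected cells RNA28SN4 and RNA45SN4 held 825 reads and RNA28SN5 and RNA45SN5 held 775, and in GFP-(GP)10 RNA28SN5 and RNA45SN5 held 245 reads, as did RNA28SN1 and RNA45SN1. The lists of experiment 1 use older names for the repeat copies.

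Of 16 gene lists, tested by the number of names with a region, tRNA names were fewer in GFP-(GR)50 replicate 1 than in GFP, 3 of 80 against 45 of 190 (adjusted exact p = 0.000740), the 1 list of 10 testable lists to pass. Against untransfected cells, 4 of 15 lists were higher in GFP-(GR)50 replicate 2: 7SL, 7SK, Y and vault RNA with RPPH1 and RMRP (33 of 484 names against 2 of 732, adjusted exact p = 2.93e-10), tRNA (15 against 4, adjusted exact p = 0.00791), cytosolic ribosomal proteins (7 against 0, adjusted exact p = 0.0105) and snoRNA and scaRNA (14 against 5, adjusted exact p = 0.0172). Against GFP-(GP)10, the 7SL and 7SK list was higher (33 against 2 of 181, adjusted exact p = 0.0105), and nuclear rRNA names (29 of 484 against 24 of 181, adjusted exact p = 0.0172) and tRNA names (15 against 18, adjusted exact p = 0.00875) took smaller shares of the names, 3 of 14 lists. Adjusted over the list alone, within each comparison, the counts were 1, 4 and 3 as well as over all 39 tests. Most of the 33 names of the 7SL and 7SK list are 7SK RNA and its copies, which share reads. The 2 names in untransfected cells and in GFP-(GP)10 are 7SK and RN7SK, which name 1 region. The tests count such names as independent, so they do not show breadth over the list. With at least 2 regions asked of each name, none passed against untransfected cells. The differences there were 8.16 points for the 7SL and 7SK list, 8.91 for tRNA and 6.12 for ribosomal proteins. In the regions at or above each list's median reads the ribosomal protein list did not pass (1.35 points, adjusted exact p = 0.162). Against GFP-(GP)10, the 7SL and 7SK list did not pass in the regions at or above the median reads (7.96 points, adjusted exact p = 0.0707) or with 2 regions per name (8.16 points, adjusted exact p = 0.745). At the same number of top regions, neither rRNA names (-0.782 points, adjusted exact p = 1) nor tRNA names (-9.11 points, adjusted exact p = 0.316) passed. Against the 3 control lists together the differences were 1.57 and -1.64 points (adjusted exact p = 0.529 for each).

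The remaining lists did not pass in any comparison over all regions, and members of the passing lists are given beside them. snRNA had 14 names in GFP-(GR)50 replicate 1, 34 in GFP, 23 in GFP-(GR)50 replicate 2, 26 in untransfected cells and 8 in GFP-(GP)10, and at the same number of top regions they were a larger share of names in GFP-(GR)50 replicate 2 than in GFP-(GP)10, by 13.3 points (adjusted exact p = 0.00557). RNU1-1, the U1 spliceosomal RNA, had 14.2, 29.1, 17.8, 31.5 and 5.50 reads in the same order, and RNU1-2 and RNU1-3 had 13.2 each in GFP-(GR)50 replicate 1 and 29.1 and 29.0 in GFP. These U1 copies share multimapping reads, so their names are not independent in the test. SNORD3A, the U3 snoRNA that guides cleavage of the rRNA precursor, had 5.34, 18.7, 29.8, 13.6 and 8.81. The further U3 copies SNORD3B-1, SNORD3B-2 and SNORD3C had 28.3, 27.8 and 26.6 reads in GFP-(GR)50 replicate 2 and 17.1, 16.99 and 17.99 in GFP. RN7SKP255 had 17.7 reads in GFP-(GR)50 replicate 1, 5.85 in GFP and 49.5 in GFP-(GR)50 replicate 2. Nucleolar and ribosome biogenesis factors had 3 names in GFP-(GR)50 replicate 2, 1 in untransfected cells, 1 in GFP and none in the other lists. Translation factors had 4 names in GFP-(GR)50 replicate 2, 4 in untransfected cells, 3 in GFP and 1 in GFP-(GP)10. EEF2 (chromosome 19, 3980583 to 3980698) had 11 reads in its best region in GFP-(GR)50 replicate 2 and 5 in GFP. Histone genes had 4 names in GFP-(GR)50 replicate 2 and 2 in GFP, with 5.50 and 8.50 reads at HIST1H3B.

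Nuclear lncRNA had 4 names in GFP-(GR)50 replicate 2, 3 in untransfected cells and 1 each in GFP and GFP-(GP)10. MALAT1, a nuclear speckle RNA, had 15 reads in its best region in GFP-(GR)50 replicate 2, 17 in untransfected cells, 13 in GFP-(GP)10 and 10.9 in GFP. NEAT1, the scaffold of paraspeckles, had 8 in GFP-(GR)50 replicate 2 and 26 in untransfected cells. Stress granule proteins had 1 name in GFP-(GR)50 replicate 2, 3 in untransfected cells and 1 in GFP-(GP)10, and the region in ATXN2 (chromosome 12, 111553559 to 111553604) had 10.5, 17.1 and 10 reads. ALS and FTD genes had 1, 2 and 2 names in these lists. MATR3 had 11, 22.3 and 7 reads, and HNRNPA2B1 was listed with 8 reads in untransfected cells and 5 in GFP-(GP)10. The hnRNP and SR splicing factors had 1, 2 and 2 names, and the cytoskeleton list had ACTG1 in GFP-(GR)50 replicate 2 (7 reads) and GFP-(GP)10 (5 reads). Heat shock and chaperone genes had 3 names in untransfected cells and none elsewhere, and no mitochondrially encoded gene had a region in any list.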

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

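Chosen after the results were seen were all tests of this part except that of the read minimum in the upper regions and the 7SK difference at the same number of top regions, which was set beforehand although its bound was written afterwards; those of exonic regions of 5 to 7 reads and without repeats in untransfected cells were chosen after seeing the data but had their bounds written before their values. The effect of GFP-(GR)50 on the share of regions in rRNA was larger in experiment 1 than in experiment 2, by 1.20 on the log2 scale of odds ratios against untransfected cells (adjusted exact p = 0.00939, exact test of homogeneity) and by 3.47 against GFP-(GP)10 (adjusted exact p = 4.27e-19). The effect on tRNA also differed, with log2 ratios of odds ratios of -8.69 (adjusted exact p = 2.71e-35) and -3.16 (adjusted exact p = 3.39e-05). The contrasts are not alike, since the control of experiment 1 is GFP and those of experiment 2 are untransfected cells and GFP-(GP)10, and the experiments differ in RNase I amount. Names of the rRNA repeat differ too, and only the lists of experiment 2 hold regions on the extra contig. Outside the annotation, 19.2% (19.0 to 19.4) of the listed reads of GFP-(GR)50 replicate 2 lay on the extra contig, above 10.9% in untransfected cells and 14.9% in GFP-(GP)10.

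The first pattern is the higher share of reads in rRNA in the GFP-(GR)50 lists. The minimum of 5 reads could raise a share by removing other RNAs; the test written beforehand left 11.01 points in experiment 2 but cannot decide, since the minimum acts most on the controls there, whose lists have fewer reads. Where a control had more regions outside rRNA, its minimum was raised until it had no more than GFP-(GR)50, and the smallest difference was still 23.4 points, above the bound of 5 points. Unannotated rRNA copies cannot hide the reads of the controls, whose lists hold the smaller shares on the extra contig, and with them counted the difference from untransfected cells was 40.5 points. Total depth, which is not given, and differences between cultures and gel pieces stay open, and beside them binding of poly-GR to rRNA is a hypothesis.

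The second pattern is the larger number of 7SK regions in the GFP-(GR)50 lists. If depth alone brought them over the minimum, the excess should end at the same number of top regions. It did not in experiment 2, where the list of GFP-(GR)50 replicate 2 was cut to 183 regions. There the 7SK share was higher by 6.01 points against each control (adjusted p = 0.0108 for each, two-sided Fisher's exact test). Against GFP the difference was 4.92 points (adjusted exact p = 0.0326), but 183 regions are the whole list of GFP-(GR)50 replicate 1. That difference therefore cannot decide the question. Against untransfected cells, uniquely mapping reads at RN7SK had an odds ratio of 14.6 outside rRNA and 7.77 over all such reads. Sharing of reads between near-identical copies is thus not the whole cause of the larger share of 7SK reads there. Among regions with at least 5 uniquely mapping reads the odds ratio of 7SK was 17.9 (2.28 to 140), with 10 regions against 1. This cannot decide the cause of the number of regions. The untransfected list had 7 uniquely mapping reads at RN7SK, its only 7SK region, against 58 in GFP-(GR)50 replicate 2, too few for copies to reach the cut readily. Sharing as the whole cause of the number of regions therefore stays open against each control. Against GFP and GFP-(GP)10 the smaller odds ratio was 3.31 (0.421 to 26.0), and single copies may carry no separate binding. Binding of 7SK RNA by poly-GR stays a hypothesis.

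The third pattern is the higher exonic share of protein-coding regions in GFP-(GR)50 replicate 2. Among regions of 5 to 7 reads the odds ratio against untransfected cells was 4.60 (2.94 to 7.21), but the bound written for it was wrong, since regions that depth adds lie at these counts, so this decides nothing. With the same number of top protein-coding regions from each list, the odds ratio was 5.803 (3.55 to 9.49) against untransfected cells. There the GFP-(GR)50 list enters whole, with 96 of 283 exonic, against at most 44 exonic regions of untransfected cells. The shares could not have become equal, so this value decides nothing. Against GFP-(GP)10, where the GFP-(GR)50 list was cut to 88 regions, the odds ratio was 2.55 (1.21 to 5.37). At or above each list's median reads that difference, 14.7 points, did not pass. Depth therefore stays open. An excess of intronic regions opposite repeats is excluded against untransfected cells, with an odds ratio of 6.64 (3.16 to 13.9) without repeats, and stays open against GFP-(GP)10, at 2.42 (0.723 to 8.13). A preference of poly-GR for exons stays a hypothesis beside depth and differences between cultures.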

How the results depend on the processing

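The alternatives with matching regions, uniquely mapping reads, every gene name, repeats, regions of 5 to 7 reads, all reads at RN7SK, experiment as a block, top protein-coding regions and 7SK regions with 5 uniquely mapping reads were chosen after seeing the data. Over 402 results and settings, the main results kept direction and side of the threshold, or moved little, in 93 cases. They lost the threshold in 8, gained it in 4, moved in 37 and reversed in 7; single classes and lists did so in 200, 22, 16, 6 and 9. Where no cause is named, the cause was not tested. Differences are in percentage points, in the order GFP-(GR)50 replicate 1 against GFP, then replicate 2 against untransfected cells and against GFP-(GP)10.

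The rRNA share of reads stayed higher in GFP-(GR)50 in every setting run. It was higher by 30.7, 25.5 and 12.2 in the regions at or above each list's median reads, by 28.9, 12.5 and 13.3 at the same number of top regions, by 41.6 and 20.1 against the 3 control lists together, and by 14.2, 21.8 and 11.5 with rRNA genes alone. Matching regions gave 40.5 and 22.4 in experiment 2, and uniquely mapping reads 79.0, 45.1 and 43.3. The rRNA share of regions against GFP-(GP)10 reversed to 15.3 at the same number of top regions and to 5.19 against the control lists together, and passed the test at -8.00 with matching regions. With rRNA genes alone the 3 differences were 3.59, -0.724 (reversed) and -9.35, and weighted by covered length the first was 16.3. Weighted so, the tRNA share of regions moved to -10.4, 0.966 and -2.86. Against untransfected cells 7SK RNA moved to 1.35, exons to 3.31 and unannotated sequence to -6.29. Leaving out either GFP-(GR)50 replicate leaves 1 library, with no spread among samples.

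At the same number of top regions, 4 classes passed against untransfected cells and 5 against GFP-(GP)10. The list of GFP-(GR)50 replicate 1 enters whole there, and the cut leaves GFP 0 exonic regions. The exon share passed in experiment 1 at 5.46, which therefore decides nothing, and at 10.7 outside rRNA. It reversed to -0.546 and -1.09 in experiment 2 and the repeat share against GFP-(GP)10 to -7.65, the exonic share of protein-coding regions was 1.67 and reversed to -1.52, and the overlap of GFP-(GR)50 replicate 2 with replicate 1 reversed to 27.3 more than GFP and 29.5 more than untransfected cells and passed at 34.4 more than GFP-(GP)10. By construction this setting removes the low regions of the longer lists. The snRNA share against GFP-(GP)10 passed at 7.65 (7.61 at or above the median reads) and snRNA names at 13.3. U1 copies among them share reads and are not independent regions or names. 2 gene lists passed against untransfected cells. rRNA names in experiment 1 passed at 29.8 at or above the median reads, 20.6 against the control lists together and 50.6 with 2 regions per name.

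Against the 3 control lists together, 7, 5 and 5 classes passed. snRNA and unannotated regions in experiment 1 reversed to 4.30 and -13.6 and tRNA against untransfected cells to -9.28, since these controls differ in tRNA. Exonic shares in experiment 1 passed at 50.4. 3 and 2 gene lists passed in the first and second comparisons, snRNA names in experiment 1 reversed to 13.3, tRNA names against untransfected cells to -1.64 and rRNA names against GFP-(GP)10 to 1.57.

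In the regions at or above the median reads, 2 and 2 gene lists passed in the first and second comparisons, 6 names lay in both GFP-(GR)50 lists alone, the exonic share against GFP-(GP)10 was 14.7 and no longer passed, and neither did the overlap with GFP, at -2.48. Without repeats, 5 and 5 classes passed in experiment 2 and the exonic share against GFP-(GP)10 was 21.7, which did not pass. Against untransfected cells introns (-3.36), unannotated sequence (-1.31) and snoRNA (1.63) no longer passed in this setting. Against GFP-(GP)10 introns (5.23) and unannotated sequence (-5.52) passed there. Outside rRNA, the overlap of replicate 1 exceeded GFP by 8.70, which did not pass, and that of replicate 2 differed by -9.24 from GFP, -18.3 from untransfected cells and, reversed, -7.48 from GFP-(GP)10. The differences of replicate 2 decide nothing, since replicate 1 held 69 regions outside rRNA against 393, 1267 and 267 in these controls. With 2 regions per name, 2 and 0 lists passed, and the 7SL and 7SK list against GFP-(GP)10, at 8.16, did not, nor did it at 7.96 at or above the median reads. The 13 names became 22 with every gene name, 53 with regions in place of genes, and 32 to 314 when a GFP-(GR)50 replicate was left out, by construction since 1 list is then asked for.

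Not run were alternatives for sequence composition and for read counts per gene, which were not analysed here. Those for the number of regions, which they fix, and pooled controls for the shared names, which are the main setting, give no other value. With libraries as units and experiment as a block, the rRNA share was higher in GFP-(GR)50 by 28.6 for reads (exact permutation p = 0.167, the smallest that 6 arrangements allow) and by 21.2 for regions (exact permutation p = 0.500). Libraries are not paired one to one. Over all uniquely mapping reads, the odds ratios at RN7SK became 2.43, 7.77 and 1.92, and only that against untransfected cells still passed. With the same number of top protein-coding regions the exonic shares differed by 12.5, 25.8 and 15.9, and no call changed. The shares behind 25.8 could not have become equal, so that value decides nothing. With at least 5 uniquely mapping reads per region, the 7SK share differed by 2.08, 1.52 and 1.12, and again only that against untransfected cells passed.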

Other observations

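The comparisons of scattered copies and of regions opposite repeats in this part, and the test of the latter, were chosen after the values were seen. Copies of rRNA sequence scattered over chromosomes other than 21 and Y, 5S copies left out, were listed 79 times in GFP-(GR)50 replicate 1 and 93 times in GFP-(GR)50 replicate 2, against 37 in GFP, 21 in untransfected cells and 12 in GFP-(GP)10. Of these, 51 and 56 resemble 28S rRNA in the GFP-(GR)50 lists and 25 and 33 resemble 18S rRNA, while 14 resemble 28S and 23 resemble 18S rRNA in GFP, 10 and 11 in untransfected cells and 6 and 6 in GFP-(GP)10. They held 40.3% (37.9 to 42.7) of the reads that map to one place in GFP-(GR)50 replicate 1 and 21.9% (21.02 to 22.7) in GFP-(GR)50 replicate 2, against 2.78% (2.38 to 3.22) in GFP, 1.41% (1.17 to 1.68) in untransfected cells and 1.84% (1.23 to 2.65) in GFP-(GP)10. The region of 28S type on chromosome 5 (71850916 to 71851120) had 153 such reads in GFP-(GR)50 replicate 2, 49 in replicate 1 between 71850918 and 71851118, and 11 in untransfected cells. Another in GCNT1 on chromosome 9 (76571739 to 76572035) had 140 in GFP-(GR)50 replicate 2.

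Regions that lie on the strand opposite an annotated repeat element made up 71.2% of the untransfected list, 39.7% of GFP-(GP)10 and 40.5% of GFP-(GR)50 replicate 2, but 6.36% of GFP and 6.01% of GFP-(GR)50 replicate 1. The difference of GFP-(GR)50 replicate 2 from untransfected cells was -30.7 points (adjusted p = 4.16e-44, two-sided Fisher's exact test). RMRP, the RNA of RNase MRP, which cleaves the rRNA precursor, was chosen after its values were seen. It had 31.5 reads in GFP-(GR)50 replicate 2, 8 in GFP-(GR)50 replicate 1 and 17 in GFP, and was not listed in the other controls.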
